A study of Homo sapiens with 2 samples.

How the data were processed

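RNA was measured by sequencing in A549 cells, a human lung adenocarcinoma line that the labels class as non-small cell lung cancer. One library came from cells with an shRNA against LacZ, a bacterial gene that human cells lack, and serves as the control. The other came from cells with an shRNA against PSPC1. Each group holds 1 library. Cells grew in medium with 10% serum and 1% penicillin and streptomycin, total RNA was extracted with Trizol, and libraries were made by a standard Illumina protocol, per the labels' protocols. Whether the protocol selected poly(A) RNA or kept the strand is not given in the sources used here.

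The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.7 and Cufflinks 2.1.1. Each library has 1 deposited file of transcripts, and each transcript carries FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), a lower and an upper bound of a 95% interval and a coverage. These FPKM, coverage and interval values were computed by the authors, per the attribute names in the deposited files. The files hold annotated RefSeq transcripts, 43212 in the control and 43207 in the knockdown file, beside transcripts that were assembled from the reads, 39901 in the control and 47148 in the knockdown file. Assembled transcripts with a single exon mostly carry no strand, which was the case for 29208 in the control and 36255 in the knockdown file. The genome build is not given in the sources used here. The names of unplaced scaffolds and the positions of genes in the files are those of GRCh37, and all coordinates below are the files' own.

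Transcripts were joined to genes by their RefSeq accession or gene identifier. A table of RefSeq genes on the GRCh38.p14 assembly and GENCODE release tables were used for names, gene classes and GC content only, and no coordinate was taken from them. Another 337 annotated accessions were placed by an intron shared with a gene. An assembled transcript with a strand was given to the gene with which it shared most introns, or in which at least 0.5 of its exon bases lay. Assembled transcripts without a strand were left unassigned. Rows in both files were found for 26522 genes, of which 25017 had a symbol in the name table. Another 2 genes had no row in the control file and 4 had none in the knockdown file, and these were left out.

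A gene's value was the sum of the FPKM of its transcripts, with an interval half-width equal to the root of the summed squared half-widths. Log2 ratios are knockdown over control with a pseudocount of 1, so they understate the change of genes with low FPKM. With 1 library per group no test between the groups is possible, no p-value is given, and no difference has a replicate check. The intervals cover counting and assignment error within a library only. In place of a test, a rule of size was set: at least 1 FPKM in the library where the gene is higher, a log2 ratio of at least 1 in either direction, and intervals that do not overlap. For transcripts, the rule asked for a gene at 5 FPKM or more in both libraries, a change of at least 0.3 in the transcript's share of its gene's FPKM, and intervals that do not overlap. The words rose and fell are used only of genes past the rule of size.

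A second measure was added after the data were examined, because summed FPKM appeared to depend on which transcripts were assembled in each file. A short transcript has few positions at which a fragment can start, so a few fragments give it a high FPKM. When an assembled short transcript appears in 1 file only, the summed FPKM of its gene differs although the number of fragments need not. The interval of a transcript alone at its locus follows from its number of fragments, and the fragment number implied by each interval was whole within 0.02 for 94.2% of 29032 such transcripts with 5 to 200 fragments in the control file and for 94.5% of 35288 in the knockdown file. From these the depth was estimated at 56100000 fragments for the control and 57000000 for the knockdown library, with mean fragment lengths of 161 and 163 bases. FPKM times effective length, summed over a gene's transcripts, then gave its estimated fragments, which were put back on the FPKM scale with the longest annotated transcript. At these depths, 1 FPKM over a transcript of 2000 bases stands for about 103 fragments in the control and 105 in the knockdown library, and 100 fragments give an interval of 20% to each side.

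In all, 25 gene lists were fixed before the data were examined, together with the rules of size, the rule for named genes and most alternatives. The lists cover paraspeckle proteins, nuclear long non-coding RNAs, epithelial and mesenchymal genes, TGF-beta signalling and TGF-beta targets, stemness, S phase, G2 and mitosis, p53 targets, interferon-stimulated genes, NF-kB and inflammatory cytokines, cholesterol synthesis, the integrated stress response, NRF2 targets, hypoxia and glycolysis, extracellular matrix, splicing and 3' end processing factors, alveolar and airway differentiation, markers of leukocytes and of fibroblasts and endothelium, mitochondrially encoded genes, histones, ribosomal proteins and reference genes. A list's median over members at 1 FPKM or more in either library was set against the medians of 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is not a test. Some lists share members.

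The named genes are PSPC1, up to 4 members per list and direction past the rule of size or else the most abundant pair, the 12 protein-coding genes with the highest and the 12 with the lowest log2 ratio among those past the rule with at least 10 FPKM, ACTB and GAPDH, and up to 6 transcripts with the largest change in share. After the data were examined, genes were also named by a stricter rule: past the rule of size by both measures, above 0 FPKM in both libraries, and no more than 0.2 of the FPKM in intron chains present in 1 file only. Other list members named as examples were chosen after their values were seen. An FPKM of exactly 0 can be a failed estimate in these files, since abundant genes of the mitochondrial genome are among those at 0. Such genes are said to be listed at 0, without a fold. XIST and Y-linked genes were left out, and some genes that the rule names are not reported here.

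Alternatives were 2 other pseudocounts, centring on the median, upper-quartile scaling, rescaling to a fixed sum without mitochondrial genes, the most abundant transcript alone, leaving out transcripts under 300 bases, other limits on low values, other interval rules, protein-coding genes only, a lower limit on size and other limits on transcript shares. The rule of size and the list percentile were tested on simulated libraries with the real expression levels and depths and with counting error only. Of 50 genes changed by 3 times, 43 were recovered. Of 50 changed by 4 times and 50 by 8 times, 49 each were recovered, and 0 of 50 changed by 1.5 times passed. Among 11066 unchanged genes 0 passed, and 3 of 100 unshifted lists of 40 genes fell outside the central 95% of random lists. Differences between cultures and in assembly were not simulated, so these counts do not give the rate of false calls in the real libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.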

Results

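Gene expression in A549 lung adenocarcinoma cells with an shRNA against PSPC1 was compared with that in cells with a control shRNA against LacZ. The aim was to describe which transcripts differ between the libraries, and protein was not measured. PSPC1 (paraspeckle component 1) is an RNA-binding protein of the same family as NONO and SFPQ and is found in paraspeckles, nuclear bodies built on the long non-coding RNA NEAT1. Each group had 1 library, so no difference below has a replicate check. The depth implied by the deposited intervals was about 56100000 fragments in the control and 57000000 in the knockdown library. Each library had 11452 genes at 1 FPKM or more, and 11080 genes reached that level in both. The median log2 ratio of those 11080 genes, knockdown over control, was 0.01, and 92.3% of them lay within 0.5 of 0 by estimated fragments. Values after ± are half-widths of 95% intervals from Cufflinks and cover error within a library only.

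PSPC1 was lower in the knockdown library, as its label says. Its summed FPKM was 31.5 ± 1.25 in the control and 17.7 ± 0.858 in the knockdown library, which is 56.3% of the control level and a log2 ratio of -0.79, with bounds of -0.92 and -0.67 from the intervals. By estimated fragments the log2 ratio was -0.80, from 3031 fragments in the control and 1709 in the knockdown library. The difference did not reach the 2-fold limit of the rule of size. The gene lies on the minus strand of chromosome 13, from 20248892 to 20357159. An assembled transcript of 9 exons with the same introns in both files carried most of the signal, with 27.0 FPKM in the control and 17.7 in the knockdown library. The annotated coding transcript of 10 exons stood at 4.49 FPKM in the control and was listed at 0 in the knockdown library, and both annotated non-coding transcripts were listed at 0 in both. The partner proteins NONO (133 and 142 FPKM) and SFPQ (145 and 159 FPKM, control and knockdown) had log2 ratios of 0.09 and 0.14.

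Among the genes that fell by both measures were CXCL3, SERPINA3, CFB, TIMP2 and CKS1B, with FPKM in the knockdown library well under those in the control. By summed FPKM, 201 genes were higher and 228 lower past the rule of size, but 105 of the higher and 93 of the lower ones were listed at 0 in the other library. Of those above 0 in both libraries, 96 higher and 135 lower, the second measure (estimated fragments) also passed for 26 and 59. With no more than 0.2 of the FPKM in intron chains seen in 1 file only, 15 higher and 45 lower genes remained, a stricter set chosen after the data were examined. In it, the chemokine gene CXCL3 fell from 34.5 ± 1.57 to 9.61 ± 0.823 FPKM (log2 ratio -1.74). SERPINA3, an acute-phase serine protease inhibitor, fell from 38.0 ± 1.56 to 10.7 ± 0.820 FPKM (-1.74). The vitamin B12-binding protein gene TCN1 fell from 13.99 to 4.14 FPKM, and complement factor B (CFB) fell from 86.5 ± 1.58 to 37.9 ± 1.04 FPKM. TIMP2, an inhibitor of matrix metalloproteinases, fell from 17.6 to 7.06 FPKM. CKS1B, a subunit of cyclin-dependent kinases, fell from 85.8 to 32.0 FPKM, and TPPP3, a tubulin-binding protein gene, fell from 10.2 to 3.78 FPKM.

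Fewer genes rose by both measures. Of the stricter set, 4 protein-coding genes reached 10 FPKM in the knockdown library. FXYD2, a regulatory subunit of the sodium pump, rose from 5.51 ± 0.979 to 43.3 ± 2.73 FPKM (log2 ratio 2.77). SAMD11 rose from 3.77 ± 0.349 to 11.8 ± 0.620 FPKM (1.43), the insulin-like peptide gene INSL4 from 30.1 ± 2.33 to 77.9 ± 3.75 FPKM (1.34), and LITAF, which encodes an endosomal membrane protein, from 24.4 ± 1.08 to 52.4 ± 1.8 FPKM (1.07). The 12 lower genes of this rule also held H3C14, H4C14, H4C15, EIF5AL1 and MT1F, which have near-identical copies elsewhere in the genome, so that their fragments could have been split differently in the libraries. MT1F, a metallothionein, stood at 10.8 and 3.29 FPKM.

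**Figure D1:**
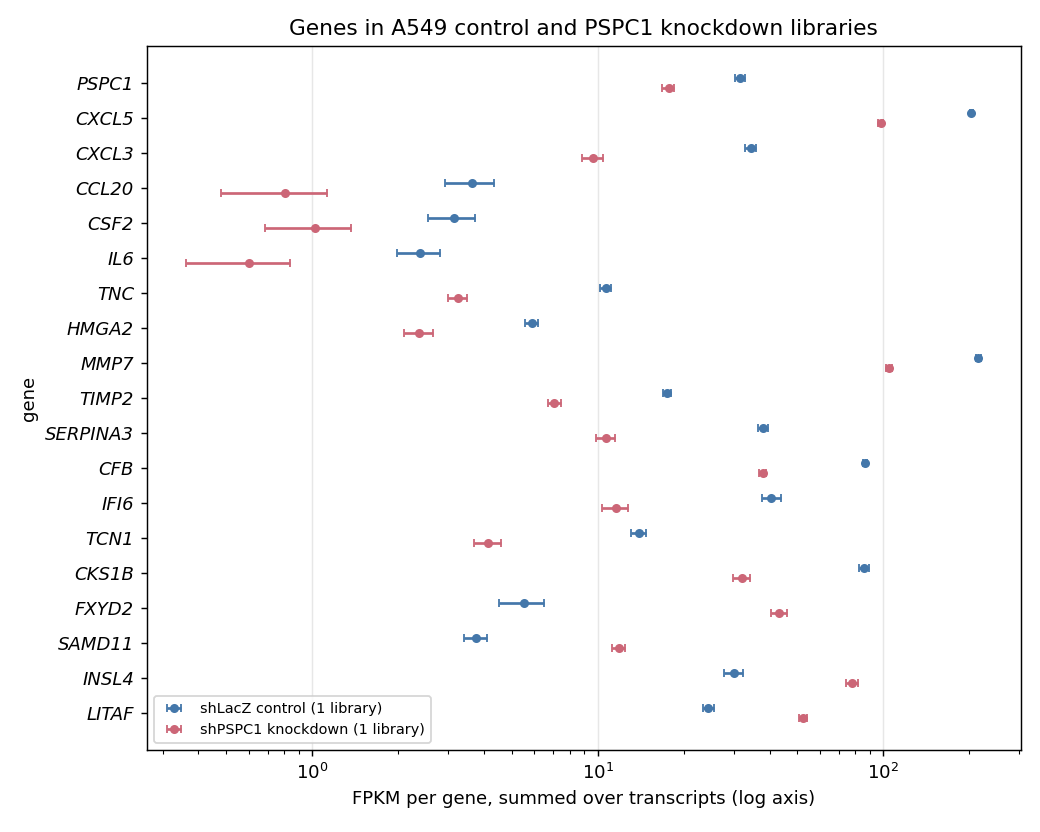
FPKM per gene on a log axis in the shLacZ control library (blue) and the shPSPC1 knockdown library (red), 1 library each, for PSPC1 and 18 genes past the rule of size by both measures. Bars are half-widths of the Cufflinks 95% intervals combined over transcripts. CXCL3 stands at 34.5 and 9.61 FPKM and FXYD2 at 5.51 and 43.3 FPKM in the control and knockdown libraries.

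Inflammatory cytokine genes were lower as a group. Of 35 measured members of the NF-kB and inflammatory cytokine list, 5 fell past the rule by both measures and 0 rose, and 24 had a log2 ratio below 0. The list's median was -0.23, at percentile 0 of 10000 matched random lists, and -0.42 by estimated fragments, also at percentile 0. CXCL3 led the list, followed by the chemokine CCL20 (3.64 to 0.802 FPKM), the cytokine IL6 (2.39 to 0.601 FPKM) and the chemokine CXCL5 (203 ± 2.51 to 97.9 ± 1.73 FPKM). CSF2, which encodes the growth factor GM-CSF, fell from 3.14 to 1.03 FPKM. CXCL8 stood at 204 and 117 FPKM, short of the limit. NFKB1, RELA and NFKBIA, which encode subunits and an inhibitor of NF-kB itself, had log2 ratios of -0.08, 0.03 and 0.10 by estimated fragments. The related gene NFKBIZ, which is not in the list, fell from 6.14 to 2.43 FPKM. Its log2 ratio was -1.06, and -1.86 by estimated fragments, but 0.33 of its FPKM lay in intron chains present in 1 file only.

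Interferon-stimulated genes were lower with few passing the rule. Of 44 measured members, IFI6 alone fell, from 40.6 ± 3.10 to 11.6 ± 1.24 FPKM, and 0 rose, but 39 of the 44 had a log2 ratio below 0. IFI6 is not in the stricter set, since 0.489 of its FPKM lay in intron chains present in 1 file only. The median was -0.35 and lay at percentile 0, against a central 95% of random medians from -0.07 to 0.09. ISG15, a ubiquitin-like protein, stood at 18.6 and 10.1 FPKM, and B2M, the light chain of class I HLA, at 415 and 282 FPKM. HLA-B stood at 41.8 and 21.6 FPKM, a value that depends on how fragments were shared among HLA genes.

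Mesenchymal, matrix and TGF-beta target genes were also lower as groups. In the mesenchymal list 21 of 27 measured members had a log2 ratio below 0 and the median was -0.41 (percentile 0). TNC, the matrix glycoprotein tenascin C, alone passed the rule and fell from 10.7 ± 0.442 to 3.24 ± 0.241 FPKM, but 0.689 of its FPKM lay in intron chains present in 1 file only, so it is not in the stricter set. The list of TGF-beta targets had a median of -0.23 (percentile 0) over 37 measured members, of which TNC and HMGA2, a chromatin protein gene (5.89 to 2.38 FPKM), fell and 0 rose. TGFBI, an extracellular matrix protein, stood at 464 and 241 FPKM, just short of the limit. Of the 37, 28 had a log2 ratio below 0, and 31 by estimated fragments. ID1, a TGF-beta and BMP target of the same list, went the other way, with 149 and 209 FPKM, as did ID2, with 19.3 and 34.1 FPKM. Over 47 measured members of the matrix and adhesion list the median was -0.27 (percentile 0). The matrix metalloproteinase MMP7 fell from 216 ± 4.0 to 104.7 ± 2.77 FPKM and TIMP2 fell as given above, and 0 rose. The mesenchymal and matrix lists share 10 members, and the mesenchymal and TGF-beta target lists share 4. Over the 32 measured ligands, receptors and SMADs of the TGF-beta pathway the median was -0.07 (percentile 5.13) and 0 members passed. Under alternatives that median ranged from -0.23, over members at 5 FPKM or more, to 0.025, after rescaling without mitochondrial genes. The most abundant members of that list were FSTL3, at 56.0 and 40.1 FPKM, and SMAD2, at 39.0 and 34.1 FPKM.

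Epithelial genes did not go the opposite way. Their list of 22 measured members had a median of -0.24 (percentile 0.01) by summed FPKM and -0.12 (percentile 1.64) by estimated fragments, and 0 members passed the rule. The keratin genes KRT18 (1450 and 1184 FPKM) and KRT7 (1196 and 964 FPKM) were the most abundant. CDH1, the epithelial cadherin, stood at 8.21 and 6.59 FPKM, and the mesenchymal filament gene VIM at 471 and 399 FPKM.

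Targets of NRF2, the transcription factor of the antioxidant response, were higher in the knockdown library. Their median was 0.26 over 46 measured members and 0.27 by estimated fragments, both at percentile 100, and 13 members had a log2 ratio below 0. No member reached the limit, and 5 were at least 1.5 times higher by estimated fragments while 0 were 1.5 times lower. AKR1B10, an aldo-keto reductase, stood at 1072 ± 7.29 FPKM in the control and 2131 ± 10.2 FPKM in the knockdown library, a log2 ratio of 0.99. HMOX1, heme oxygenase 1, stood at 14.9 and 28.0 FPKM, and FTL, the ferritin light chain, at 1910 and 2148 FPKM.

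**Figure D2:**
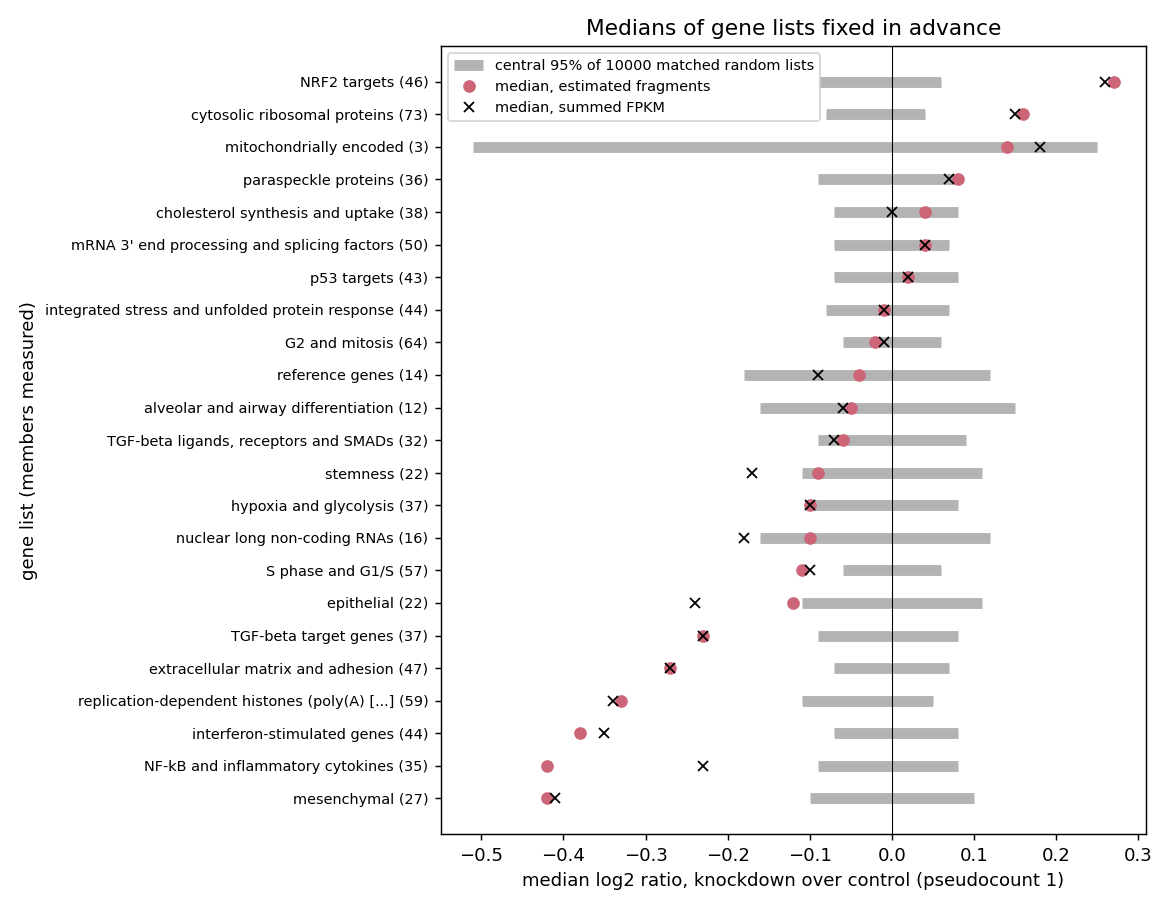
Median log2 ratio, knockdown over control, of each gene list with at least 3 measured members, by estimated fragments (red circles) and by summed FPKM (crosses), with the central 95% of 10000 matched random lists by estimated fragments (grey bars). NRF2 targets lie at 0.27 and mesenchymal genes at -0.42 by estimated fragments, both outside their grey bars.

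Ribosomal protein genes were higher as a group and histone genes lower. The 73 measured ribosomal protein genes had a median of 0.15, and of 0.16 by estimated fragments, both at percentile 100. By summed FPKM RPL10, RPS12, RPL37 and RPL9 were higher and RPLP0 and RPL6 lower past the rule. By estimated fragments RPL10, RPS12, RPL37, RPLP0 and RPL6 had log2 ratios of 0.25, 0.17, 0.24, 0.41 and 0.19, so that both lower calls turned direction. RPL9 alone rose by both measures, from 0.522 to 2.17 FPKM, with a log2 ratio of 1.06, and of 1.60 by estimated fragments, but its FPKM lay entirely in intron chains present in 1 file only. These genes have many processed copies, and their values are uncertain to that extent. Of 61 measured replication-dependent histone genes 58 had a log2 ratio below 0, with a median of -0.34 (percentile 0). Most mRNAs of these genes lack a poly(A) tail, and the list was set as a marker of poly(A) selection, so a difference in RNA selection between the libraries is not told apart from a change in the genes. Past the rule 6 were lower and H3C15 was higher. H3C14 (823 and 0.0511 FPKM), H4C14 (781 and 0.0756 FPKM) and H4C15 (780 and 0.0756 FPKM) were low in the knockdown library, and H2BC21 and H2AC21 beside them were listed at 0 there. H3C15, a copy of H3C14, stood at 558 and 1122 FPKM, and the sum of both copies at 1381 and 1122 FPKM. The sum of H4C14 and H4C15 stood at 1561 and 0.2 FPKM, so pooling that pair left the difference in place. With neighbouring genes listed at 0 in the same library, the estimates of this cluster are uncertain. H4C4 stood at 1675 and 776 FPKM, with a log2 ratio of -0.64 by estimated fragments.

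Genes of S phase and G1/S had a median of -0.10 (percentile 0.14) over 58 measured members, and of -0.009 after rescaling to a fixed sum without mitochondrial genes, which raised the median of all expressed genes to 0.10. PRIM1, the DNA primase subunit, was listed at 0 in the knockdown library against 28.6 FPKM in the control. G2 and mitosis genes had a median of -0.01 (percentile 33.0) over 64 members, of which CKS1B fell. Targets of p53 had a median of 0.02 (percentile 57.0) over 42 members, and RPS27L (217 and 241 FPKM) and PLK2 (125 and 88.3 FPKM) were the most abundant. Paraspeckle proteins had a median of 0.07 (percentile 93.6) over 36 members by summed FPKM and of 0.08 (percentile 97.9) by estimated fragments, just outside the central 95% of random lists by the second measure alone. By both measures 0 of them passed the rule.

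Lists of metabolism, stress, splicing and differentiation genes held no member past the rule. Hypoxia and glycolysis genes had a median of -0.10 (percentile 2.15, and 1.75 by estimated fragments) over 37 members, at the edge of the random range, and of -0.034 from the most abundant transcript of each gene alone, with GAPDH and PKM (968 and 1024 FPKM) the most abundant. Cholesterol genes had a median of 0 (percentile 37.9) over 38 members, led by ACLY (135 and 134 FPKM) and FADS1 (58.0 and 66.7 FPKM). The stress and unfolded protein list had a median of -0.01 (percentile 35.7) over 44 members, led by the chaperones CANX (366 and 279 FPKM) and CALR (206 and 178 FPKM). Splicing and 3' end factors had a median of 0.04 (percentile 81.7) over 51 members, led by HNRNPU (345 and 306 FPKM) and HNRNPH1 (191 and 222 FPKM). Stemness genes had a median of -0.17 (percentile 0.72) over 20 members by summed FPKM and of -0.09 (percentile 5.45) by estimated fragments, led by ALDH1A1 and ALDH3A1 (589 and 688 FPKM). ALDH1A1 stood at 3198 ± 5247 and 2714 ± 9.28 FPKM. Alveolar and airway genes had a median of -0.06 (percentile 21.9) over 13 members, led by CEACAM6 (118 and 106 FPKM) and CAV1 (92.8 and 90.2 FPKM).

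Nuclear long non-coding RNAs had a median of -0.18 (percentile 1.82) over 17 measured members by summed FPKM and of -0.10 (percentile 11.1) by estimated fragments, and 0 passed. The short RNAs RMRP and RPPH1 had the highest FPKM in that list, with log2 ratios of -0.18 and -0.36. NEAT1, the paraspeckle RNA, is annotated in the files only in its short form, at 2.23 (1.98 to 2.48) FPKM in the control and 1.93 (1.70 to 2.16) FPKM in the knockdown library. Its summed value, which entered the list median, had a log2 ratio of -0.49, and of -0.76 by estimated fragments. An assembled transcript was counted to the gene in the control file only. In the knockdown file another, from 65190269 to 65204560, spans the annotated one. It was left out, as under 0.5 of its bases lay in the gene. These log2 ratios thus leave out fragments over the gene in the knockdown library. With crossing transcripts shared out by length, the ratio over the annotated interval was 1.09. Assembled transcripts that run past the end of the short form, or follow on without a gap of 500 bases, were higher in the knockdown library. Their values are given with the additional observations.

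**Figure D3:**
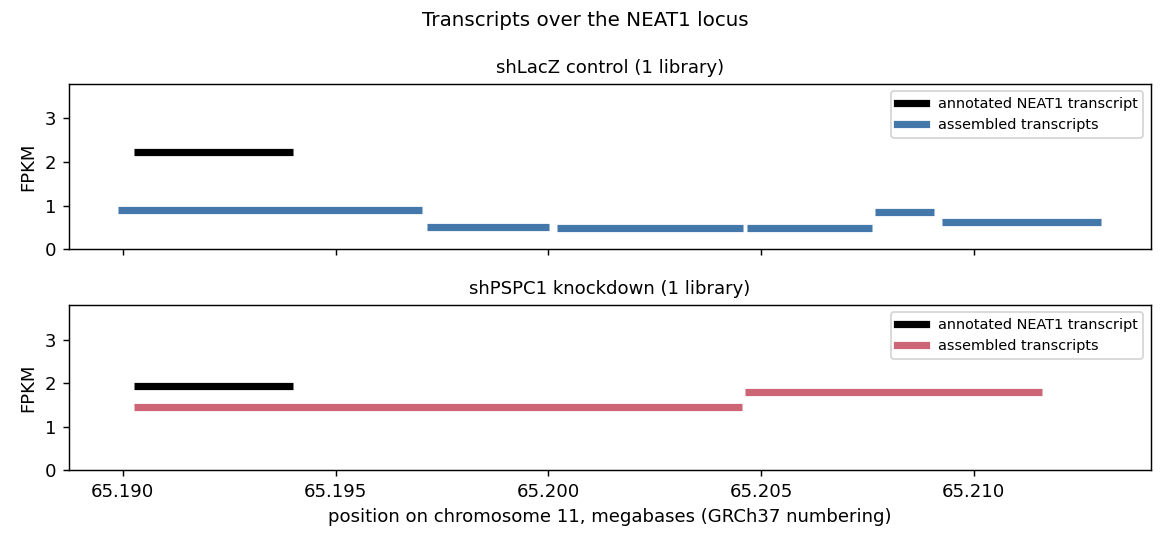
FPKM of transcripts on the plus strand or without a strand over the NEAT1 locus on chromosome 11 (x axis, megabases, positions as in the files) in the shLacZ control library (top) and the shPSPC1 knockdown library (bottom), 1 library each. The black line is the annotated short transcript, from 65190269 to 65194003, at 2.23 and 1.93 FPKM, and colored lines are assembled transcripts, which past its end lie between 0.473 and 0.887 FPKM in the control and at 1.45 and 1.81 FPKM in the knockdown library.

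Of 21 leukocyte markers, CD68 (15.6 and 8.91 FPKM) and CD14 (2.07 and 1.89 FPKM) alone reached 1 FPKM, and of 21 markers of fibroblasts and endothelium EGFL7 alone did, at 21.0 and 18.5 FPKM. Among 6 measured mitochondrially encoded genes the median was 0.18 (percentile 94.1), with COX2 listed at 0 in the knockdown library and ND4 and ND4L listed at 0 in the control. The 14 reference genes had a median of -0.09 (percentile 15.5). ACTB stood at 851 and 724 FPKM. GAPDH stood at 2283 and 1478 FPKM, with a log2 ratio of -0.63, but of 0.02 by estimated fragments, and a short assembled transcript of the gene was present in the control file only. RPLP0, also a reference gene, passed as lower by summed FPKM but had a log2 ratio of 0.41 by estimated fragments.

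Most of the largest log2 ratios by summed FPKM belonged to genes listed at 0 in 1 library. Of the 12 protein-coding genes at the top, 9 were listed at 0 in the control: ND4L, ND4, SYNJ2BP-COX16, NRG1, ABCF2-H2BK1, EMC9, YIF1B, SNAPC5 and MTIF3, with NRG1, a growth factor of the EGF family, at 21.5 FPKM in the knockdown library. The remaining 3 were UQCRB (19.2 and 221 FPKM), CHCHD3 (55.8 and 508 FPKM) and OLA1 (15.2 and 110 FPKM). Their log2 ratios by estimated fragments were 0.28, 3.19 and 0.03. CHCHD3 had an assembled transcript reaching into one of its introns in the knockdown file, where the control file holds separate assembled transcripts outside the gene count, so its change is uncertain. SYNJ2BP-COX16 and ABCF2-H2BK1 are read-through genes that overlap their neighbours. At the bottom, H3C14, H4C14 and H4C15 were followed by 9 genes listed at 0 in the knockdown library: H2BC21, H2AC21, COX2, NPY4R, MGAT4B, WTAP, PRIM1, APTX and UCHL3, with WTAP, a subunit of the RNA methyltransferase complex, at 38.4 FPKM in the control. NPY4R has a near-identical copy.

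Many transcripts differed in their share of the gene, and the count depended on how transcripts were matched between the files. Over 7217 genes with at least 5 FPKM in both libraries, 1416 annotated transcripts of 1355 genes passed the rule for a changed share, 694 with a higher and 722 with a lower share in the knockdown library. Of these transcripts 284 were listed at 0 in 1 of the libraries, and for 40 the share moved by the whole of the gene. Among the tied 40, taken in the order of their accessions, were transcripts of PLCB3, SPOP, KYAT3, TTI2 and EIF1AX. The PLCB3 transcript, which encodes a phospholipase C, stood at 8.98 FPKM in the control and was listed at 0 in the knockdown library, while the KYAT3 transcript was listed at 0 in the control and stood at 5.47 FPKM in the knockdown library. When transcripts with the same introns were pooled, the share changed for 953 of the 1416, and 3321 pooled transcripts, annotated or assembled, passed the rule. Of the transcripts named above, the pooled share changed for those of PLCB3, KYAT3 and EIF1AX but not for those of SPOP and TTI2. Shares were taken from FPKM, so a short transcript assembled in 1 file only can lower the shares of the others. The annotated UQCRB transcript went from a share of 1 to 0.029, while the gene's log2 ratio by estimated fragments was 0.28. Of the gene's FPKM, 0.893 lay in intron chains present in 1 file only. Pooling by introns does not remove this, so the counts do not measure changed isoform use alone.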

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

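The tests on transcripts found in 1 library only, on assembly differences and on numbers of intronic and intergenic pieces, and the measure of estimated fragments itself, were chosen after the result was seen.

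A signal appeared after the annotated end of NEAT1, mostly in assembled transcripts that the comparisons of genes did not use, and it was higher in the knockdown library. One assembled transcript of the control file, from 65189892 to 65197038 at 0.887 FPKM, reaches into this stretch and did enter the gene value of NEAT1 there. One of the knockdown file, from 65190269 to 65204560 at 1.45 FPKM, spans the annotated transcript and this stretch and did not enter the gene value. The annotated transcript, the short form, spans 65190269 to 65194003 on the plus strand of chromosome 11. In the 18994 bases from 65194004 to 65212997, where assembled transcripts follow one another with gaps under 500 bases, the control library had 596 estimated fragments and the knockdown library had 1564. On the FPKM scale this was 0.559 (0.513 to 0.605 from counting error) and 1.44 (1.37 to 1.52), a ratio of 2.58. Over the annotated interval itself the values were 3.0 (2.76 to 3.24) and 3.28 (3.03 to 3.53), a ratio of 1.09. The fragments of an assembled transcript that crosses the annotated end were shared out between both intervals by length. That takes coverage along the transcript to be even, so both ratios depend on it, and the intervals from counting error leave it out. The long NEAT1 isoform, on which paraspeckles are built, is known to continue past the end of the short form. The comparison rests on 1 library per group.

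The knockdown file held more strandless assembled transcripts of at least 300 bases outside the mitochondrial genome, 34168 against 27293 in the control, covering 47.5 and 37.5 megabases. They took 5.34% of the estimated fragments in the knockdown and 4.66% in the control library, at 64.0 and 69.8 fragments per kilobase. A finer splitting of the same signal is argued against, since the ratio of fragment shares was 1.14, and since where pieces of both libraries overlapped there were 16319 in the knockdown and 16376 in the control library. More unspliced precursor RNA and genomic DNA cannot be told apart here. The log2 ratio of intronic fragments minus that of intergenic fragments was -0.01. This goes with genomic DNA, but equally with a like rise of unannotated RNA in both classes. The same difference for the number of pieces was 0.18, from 13370 to 17796 intronic and from 13848 to 16283 intergenic pieces, which goes with precursor RNA. The test as planned used fragments only, although the pattern is a number of pieces. A lower limit for calling pieces in the knockdown file was not tested.

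Of the 231 genes past the rule of size and above 0 in both libraries, 146 lost their 2-fold change when estimated fragments replaced summed FPKM. A candidate cause is assembly: in the lost genes a median share of 0.6 of the FPKM lay in intron chains present in 1 file only, against 0 in the 85 kept genes, a difference of 0.6. A lost gene must differ in its mix of transcripts between the files by definition, so the test shows only that the mix differed in chains of 1 file rather than in shared ones. Few fragments are argued against as the cause, since the lost genes had a median of 1908 estimated fragments in the library where they were higher. No biological explanation was tested for this pattern.

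The lists of NF-kB and inflammatory cytokines, TGF-beta targets and mesenchymal genes were lower in the knockdown library. A trend with GC content, transcript length and expression is argued against as the whole cause. The fitted trend took only 1.4% of the variance over genes, so its removal changed little: the list medians were -0.42, -0.23 and -0.42 before and -0.40, -0.23 and -0.40 after, and the highest percentile of the 3 was then 0. Short assembled transcripts that raise summed FPKM are argued against as the whole cause, since with estimated fragments the highest percentile was 0. Estimated fragments still depend on which assembled transcripts are counted to a gene, so other differences in assembly were not tested. A difference between cultures or libraries unrelated to PSPC1, with 1 library per group, cannot be told apart from an effect of the knockdown, which stays open as the biological explanation. No second shRNA against PSPC1 is named in the labels, so effects of the shRNA on other transcripts cannot be told apart from those of lower PSPC1. Histone genes, a marker of poly(A) selection, were also lower, with a median of -0.34, and whether the libraries differed in RNA selection was not tested.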

How the results depend on the processing

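The measure of estimated fragments, the limit to genes above 0 in both libraries and the pooling of intron chains were chosen after seeing the data. The counts of higher and lower genes in the knockdown library, 201 and 228, depended on the settings. They were 305 and 339 with a pseudocount of 0.1, 76 and 88 with a pseudocount of 5, 666 and 635 from the most abundant transcript alone, 108 and 143 at 5 FPKM or more, and 513 and 625 at 1.5 times. Limited to genes above 0 FPKM in both libraries they were 96 and 135 by summed FPKM, 82 and 115 by estimated fragments and 26 and 59 by both measures. Under all 8 other settings both counts were within 1.5 times. Rescaling to a fixed sum without mitochondrial genes, which raised the median log2 ratio of expressed genes to 0.10, gave 282 higher and 229 lower genes. The PSPC1 log2 ratio stayed below 0 throughout. It was -0.58 from the most abundant transcript alone, because the annotated coding transcript then did not enter, and between -0.825 and -0.683 under the others. The count of transcripts with a changed share, 1416, became 2309 at 1 FPKM, 499 at 20 FPKM, 616 at a share change of 0.5 and 3321 with intron chains. Of 252 list medians under alternatives, 242 stayed within the bootstrap interval of the main value, 10 moved outside it and 0 of those outside the central 95% of random lists changed sign. Of the 10, 8 moved by the rescaling without mitochondrial genes, among them S phase to -0.009, hypoxia and glycolysis to -0.018 and histones to -0.24. Hypoxia and glycolysis also moved to -0.034 from the most abundant transcript alone. The medians ranged from -0.42 to -0.16 for NF-kB and inflammatory cytokines, from -0.27 to -0.14 for TGF-beta targets and from -0.47 to -0.18 for mesenchymal genes. All values in these ranges counted as staying within the bootstrap interval, so the count of 242 is a loose check. The causes of other moves were not tested. No paired analysis was possible because each group had 1 library, and no library could be left out. Depth limits genes near 1 FPKM, where 1 FPKM over 2000 bases stands for about 103 fragments.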

Other observations

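Of the mesenchymal list, 2 genes picked out after their values were seen, stood lower in the knockdown library without reaching the limit of 1 on the log2 scale with its pseudocount. COL5A1, a collagen chain, had 20.9 and 10.4 FPKM (log2 ratio -0.94, a plain ratio of 2.01), and CDH2, the neural cadherin, had 25.7 and 15.7 FPKM (-0.68) in the control and knockdown libraries. NQO1, an NRF2 target, stood at 355 and 536 FPKM. MALAT1, the nuclear RNA encoded next to NEAT1, had a log2 ratio of 0.27 by summed FPKM and of -0.05 by estimated fragments.

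Of 23 lists with a median, 11 lay outside the central 95% of matched random lists by both measures, 9 of them below and 2 above. Some of these lists share members, so these are not 11 separate results. Without the members that the TGF-beta target, NF-kB and mesenchymal lists share with one another, TGF-beta targets had a median of -0.15 over 31 genes by summed FPKM and -0.19 by estimated fragments. NF-kB and inflammatory cytokines had -0.23 and -0.42 over 33 genes, and mesenchymal genes had -0.29 and -0.41 over 23. By summed FPKM the medians with the shared members were -0.23, -0.23 and -0.41, so that those of TGF-beta targets and mesenchymal genes lay nearer 0 without them.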
